A study of Mus musculus with 8 samples.

How the data were processed

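The data are 8 samples of C2C12 mouse myoblasts: 3 libraries immunoprecipitated with a polyclonal rabbit antibody against APOBEC2 and 1 input at each of 2 times after induction of differentiation. Groups and replicate numbers were taken from the sample titles. Titles and sample characteristics give the times as 14 and 34 h, whereas the growth protocol in the labels gives harvests at 24 or 34 h; the title times are used, and the earlier time is therefore uncertain. The 2 inputs have no peak list and entered no comparison of their own.

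Reads were aligned with Subread and peaks called with MACS2 on the mm10 build, per the submitters' processing notes; versions and the calling threshold are not given in the sources used here. Peaks were called for each IP library separately against the input of its time, per the names of the deposited peak lists, and not on pooled replicates. The 12 deposited files are a peak list and a summit list for each IP library. The deposited fold is a linear ratio of IP signal to local background at the summit, as the authors' peak caller wrote it. The deposited significance columns hold −log10 p-values and −log10 q-values, and a further deposited column holds an integer score. Summit positions matched the peak lists exactly. Where peaks were filtered, this was by −log10 q or −log10 p. Fold is used to describe a region by its mean and SD over the libraries of a time. It also ranks regions by their lowest fold over libraries and orders peaks within a list. Raw folds were not tested between times. The lowest −log10 q in a list ranged from 1.58 to 2.90, so the lists did not end at an equal significance.

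The lists give no read totals. The caller's fold and p-value of each peak together fix the whole number of fragments at its summit and its background, and both were solved for 100% of peaks on the standard chromosomes, to within 0.001 on the −log10 p scale. The narrowest peak of each list was taken as the caller's fragment length. The lowest background is proportional to depth times fragment length, and background steps give the ratio of IP to input reads, which together give relative depth if all libraries were called with the same genome size. Input depth, solved separately from the 3 libraries of each time, came out at 1.0, 1.00018 and 1.00016 for 14 h and at 1.44035, 1.44062 and 1.44028 for 34 h, relative to the first. Summits stood on at least 10 fragments. Such counts limit the precision of each fold, and a site below the threshold is not shown to be unbound.

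Gene positions came from a table of NCBI RefSeq genes on GRCm38.p6, whose primary assembly is that of mm10. It gives the start and end of each gene with no strand, exons or sequence used here. The planned promoter window was therefore replaced by a window of 1 kb around either boundary of a protein-coding gene, so start and end are not told apart, and exons and introns were not separated. Planned results on sequence motifs, base composition, repeats and CpG-rich promoters were not run. There were 21887 protein-coding genes on chromosomes 1 to 19, X and Y. Of the 16 gene lists fixed before the data were examined, 15 matched in full, and 36 of 39 members of the interferon and inflammatory response list matched. The lists were muscle contraction and differentiation, myogenic transcription factors, cell cycle, replication-dependent histones, cytosolic ribosomal proteins, translation factors, oxidative phosphorylation, proteasome, interferon and inflammatory response, haematopoietic lineage, neural lineage, adipogenic with cartilage and bone lineages, TGF-beta and BMP signalling, KLF and SP transcription factors, chromatin modifiers and olfactory receptors. Another 10 lists were chosen after the data had been seen and are reported only among the additional observations.

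Peaks of libraries were merged where they overlapped by at least 1 bp, and a region was called reproducible when at least 2 of the 3 libraries of a time had a peak in it. Overlaps were compared with 1000 random circular shifts within chromosomes (one-sided), and summit positions with 100 rounds of shifts. Lists were tested with Fisher's exact test (two-sided) against all other protein-coding genes, with Benjamini-Hochberg adjustment over 16 lists and both times, and between times with an exact McNemar test and with Fisher's exact test on genes gained at 34 h, each adjusted over the 16 lists at a threshold of 0.05. Odds ratios were computed with a small constant added to each count, which raises the ratio of a list with few members found. Intervals of shares are exact binomial at 95% and cover counting error only. Values per library were compared between times with exact two-sided permutation tests, which cannot go below 0.1 with 3 against 3 libraries. Fixed alternatives were a −log10 q of at least 5, the 768 peaks of highest −log10 p in each list, 50% reciprocal overlap, summits within 100 bp, all 3 or any library, at least 2 libraries of one time and none of the other, standard chromosomes only, a window of 5 kb, each library left out in turn, and the replicate number as a block. With a library left out, a reproducible region of its time had to be in 2 of 2 libraries, and the other time kept 2 of 3. Time-specific regions then had to be in, or absent from, only the libraries left. An alternative added after the data were seen left out the 5426 genes with a boundary within 1 kb of that of another protein-coding gene.

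Named regions followed a rule fixed before the data were examined. At each time these were the 10 regions in all 3 libraries with the highest lowest-library fold at a gene boundary and the 5 highest elsewhere. To these were added the 10 highest, or all, regions in all 3 libraries of one time and none of the other, the 5 highest in all 6 libraries, 11 fixed loci, and up to 6 members per list. Not every gene that the rule takes is reported here. Coordinates are 1-based. The procedures were tested on simulated peaks: an overlap of 50% was recovered as 50.0%, 100 of 100 planted genes of a list were found at each time, and 100% of 500 simulated summits were solved. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.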

Results

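Chromatin immunoprecipitation followed by sequencing with a polyclonal rabbit antibody against APOBEC2 was carried out in C2C12 cells, a mouse myoblast line that leaves the cell cycle and fuses into myotubes when serum is lowered. APOBEC2 belongs to the AID/APOBEC family of cytidine deaminases and is expressed mainly in skeletal muscle and heart. Differentiation was induced with 2% horse serum, and chromatin was collected at times labelled 14 h and 34 h. Each time had 3 immunoprecipitated (IP) libraries and 1 input library, and the authors deposited a list of called peaks for each IP library. The lists held 768, 1327 and 797 peaks at 14 h and 2209, 5025 and 1068 peaks at 34 h. The relative depth of the IP libraries, recovered from the peak values, lay between 0.985 and 1.17 times that of replicate 1 at 14 h, and the median summit stood on 19 to 24 fragments. The labels do not say that replicates came from separate cultures, so permutation tests between libraries measure only the spread between these samples, which may be technical. Fisher's and McNemar tests run over genes and random shifts over positions, and they do not measure that spread. No library from cells without APOBEC2 or with a control antibody was used here.

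The first question was which sites were recovered at 14 h. Several of the highest regions of that time lay at genes that act in cell division. Peaks of all 3 libraries covered a boundary of Lin9, a subunit of the MuvB complex (mm10 chromosome 1, 180641015 to 180641633), with an authors' fold enrichment over local background of 41.1 ± 4.60 (SD, n = 3). The other leading regions lay at Incenp, a subunit of the chromosomal passenger complex (chromosome 19, 9899169 to 9899775, fold 45.3 ± 11.5), and at Ttk, a spindle checkpoint kinase (chromosome 9, 83834416 to 83834989, fold 46.7 ± 13.2). They also lay at Rrm2, a ribonucleotide reductase subunit (chromosome 12, 24707949 to 24708478, fold 44.7 ± 14.3), and at Bub1, a spindle checkpoint kinase (chromosome 2, 127831652 to 127832075, fold 38.5 ± 9.07). The next were Pclaf, E2f3, Mms22l, the adjoining histone genes H4c1 and H3c1, and Mybl2, with mean folds from 33.7 to 39.3. Fold is the peak caller's own value, and raw folds were not tested between times.

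Of the 48 genes of the cell cycle list, 32 (66.7%, exact 95% interval 51.6 to 79.6%) had a region of at least 2 libraries within 1 kb of a gene boundary at 14 h. Of all other protein-coding genes, 3.74% had one. The odds ratio was 50.7, with an adjusted p of 7.52e-33 by Fisher's exact test with Benjamini-Hochberg adjustment over 32 tests. Members with the highest folds were Rrm2, Bub1, E2f3, Mybl2, the mitotic kinase gene Plk1 (fold 37.7 ± 8.10) and the replicative helicase gene Mcm3 (fold 23.4 ± 4.27). The share of members with a peak was above that of other genes in 6 of 6 libraries, at 65.3% ± 10.7 at 14 h and 60.4% ± 9.55 at 34 h (SD, n = 3 each). Leaving out genes with a close neighbour, which can share a region, gave 23 of 34 members and an odds ratio of 79.5. Genes are not independent replicates, and these p-values describe lists of genes in these libraries.

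Replication-dependent histone genes were the other list above the rest at 14 h, with 18 of 63 members (28.6%, odds ratio 10.3, adjusted p = 8.66e-11, Fisher's exact test). All 18 lay on chromosome 13 in 10 distinct regions. The leading members were H3c1 and H4c1, which share a region (chromosome 13, 23761083 to 23761703, fold 39.2 ± 14.6), and H2ac12 and H2bc12, which share another (22035478 to 22035879, fold 23.1 ± 4.58). Olfactory receptor genes, expressed mainly in olfactory sensory neurons, lay below the rest, with 0 of 1106 (exact upper limit 0.333%, adjusted p = 3.89e-19, Fisher's exact test).

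The other 13 lists did not pass at 14 h. Muscle contraction and differentiation had 1 of 54 members (Myom1, an M-band protein gene), and myogenic transcription factors had 1 of 22 (Id1, an inhibitor of basic helix-loop-helix factors). Chromatin modifiers had 3 of 39 (Suz12, Ezh2 and Ehmt1). Cytosolic ribosomal proteins had 2 of 84 (Rpl4 and Rps20), translation factors 2 of 70 (Eif3k and Eif4a3) and oxidative phosphorylation 2 of 87 (Ndufb8 and Cox8a). Interferon and inflammatory response had 1 of 36, neural lineage 1 of 30 (Nes) and KLF and SP transcription factors 1 of 26 (Klf11). The proteasome (39 genes), the haematopoietic lineage (30), the adipogenic, cartilage and bone lineages (29) and TGF-beta and BMP signalling (36) had 0 each. Adjusted p for these lists ran from 0.557 to 1.0 by Fisher's exact test.

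The same question was asked at 34 h, where Ttk, Bub1, Incenp, Mms22l and the pair H4c1 and H3c1 were again among the 10 highest regions. The leading regions were at Ttk (chromosome 9, 83834377 to 83834924, fold 32.0 ± 9.07), at the adjoining genes Brd8 and Kif20a, of which Kif20a encodes a mitotic kinesin (chromosome 18, 34624407 to 34625217, fold 28.9 ± 3.88), and at Mms22l, a replication fork repair gene (chromosome 4, 24496237 to 24496723, fold 32.3 ± 8.09). The adjoining genes Ndc80 and Spdya followed (chromosome 17, 71526634 to 71527189, fold 26.4 ± 4.41), of which Ndc80 encodes a kinetochore protein. After them came Bub1, Incenp, H4c1 with H3c1, then Depdc1b, Timeless with Mip, and Haspin, with mean folds from 21.4 to 29.1. The 5 highest of the regions present in all 6 libraries were those at Ttk, Mms22l, Brd8 with Kif20a, Ndc80 with Spdya, and Bub1.

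At 34 h the cell cycle list had 29 of 48 members (60.4%, exact 95% interval 45.3 to 74.2%) against 7.17% of other genes, with an odds ratio of 19.6 and an adjusted p of 2.57e-20 (Fisher's exact test). Members with the highest folds were Bub1, E2f3, Foxm1, Plk1, Cdk1 and Rrm2, from Bub1 at 25.9 ± 4.06 to Foxm1 at 20.4 ± 3.10. Histone genes had 29 of 63 (46.0%, odds ratio 11.1, adjusted p = 3.46e-16, Fisher's exact test), in 18 distinct regions, and 27 of them lay on chromosome 13. That count fell to 14 without replicate 1 and 15 without replicate 2 of 34 h, where both remaining libraries were required. Adjusted p was then 5.99e-07 and 1.52e-08 (Fisher's exact test). Olfactory receptor genes again had 0 of 1106 (adjusted p = 3.12e-36, Fisher's exact test).

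None of the other 13 lists passed at 34 h, with adjusted p from 0.468 to 0.935. Muscle contraction and differentiation had 2 of 54 (Myom1 and Chrnb1), myogenic transcription factors 2 of 22 (Id2 and Tcf3) and KLF and SP transcription factors 4 of 26 (Sp1, Klf9, Sp4 and Sp3). Cytosolic ribosomal proteins had 8 of 84, translation factors 4 of 70, oxidative phosphorylation 4 of 87, the proteasome 4 of 39, interferon and inflammatory response 3 of 36 and chromatin modifiers 3 of 39. The haematopoietic, neural, and adipogenic, cartilage and bone lists and TGF-beta and BMP signalling had 0 each. In replicate 2 of 34 h alone, the longest list, 35.7% of translation factor genes and 35.9% of proteasome genes had a peak, against 14.0% and 14.1% of other genes. In replicates 1 and 3 of that time the shares were 7.14% and 1.43% for translation factors (other genes 7.54% and 4.07%) and 10.3% and 5.13% for the proteasome (other genes 7.53% and 4.06%).

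**Figure D1:**
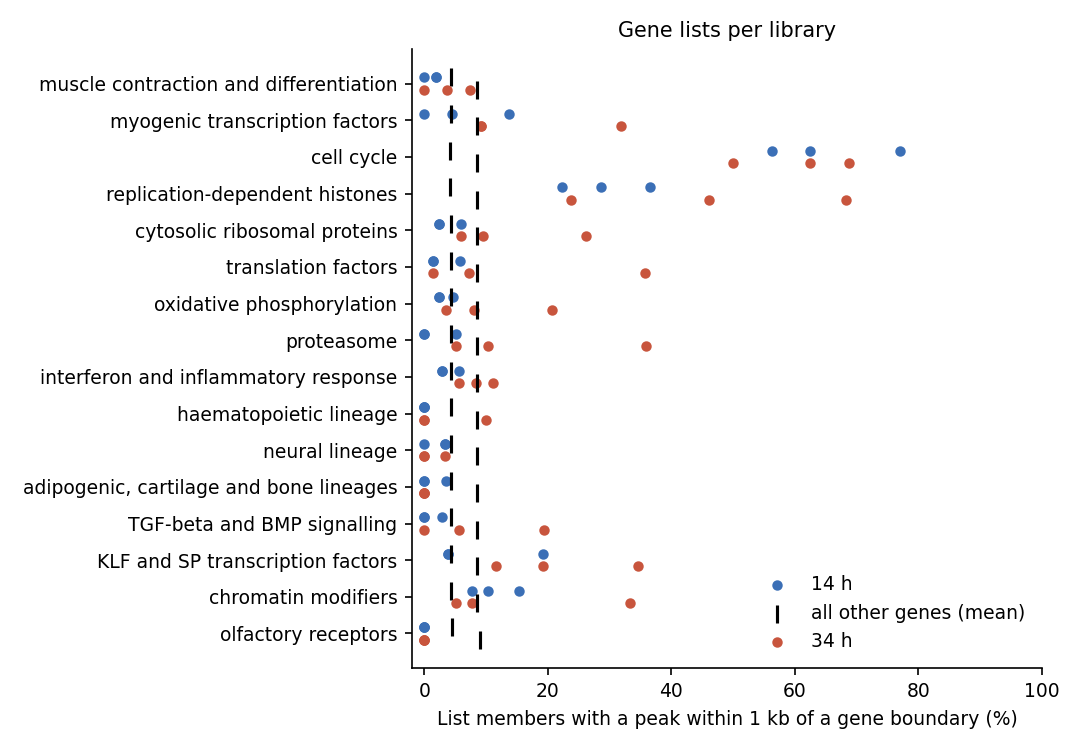
Percent of the members of each of 16 gene lists with a called peak within 1 kb of a gene boundary, per IP library (points, blue 14 h and red 34 h, 3 libraries each), with the mean share of all other protein-coding genes at each time (black bars). Cell cycle genes lie between 50.0% and 77.1% in the 6 libraries, and olfactory receptors at 0% in each.

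Loci chosen before the data were examined gave few peaks. No library had a peak within 1 kb of, or inside, Apobec2 itself, Myod1, Myog, Mef2c, Myh3, Actc1, Ccnd1, Cdkn1a or Klf4. Id1 had a peak in 2 of 3 libraries at 14 h (fold 6.42 and 6.44) and in replicate 2 at 34 h (fold 4.31). Id3 had a peak only in replicate 2 at 34 h (fold 4.53). A locus with no called peak may still have been bound below the caller's threshold.

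Called summits were concentrated at gene boundaries. At 14 h, 79.3% ± 1.59 (SD, n = 3) lay within 1 kb of the start or end of a protein-coding gene, against 3.13% after random shifts along the chromosomes. At 34 h the share was 62.1% ± 7.75. The difference was −17.2 percentage points, with no overlap between the libraries of the 2 times (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 allow). Summits elsewhere inside genes made up 9.11% ± 0.609 and 18.5% ± 6.09, and those outside genes 11.6% ± 1.47 and 19.4% ± 2.08. With each list limited to its 768 peaks of highest −log10 p, the length of the shortest list, the difference was −9.20 percentage points (exact p = 0.1). With each list split into 5 equal parts by fold, the share in the top part was 96.4% ± 1.23 at 14 h and 82.3% ± 10.8 at 34 h, and in the bottom part 46.3% ± 13.5 and 43.3% ± 5.95.

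**Figure D2:**
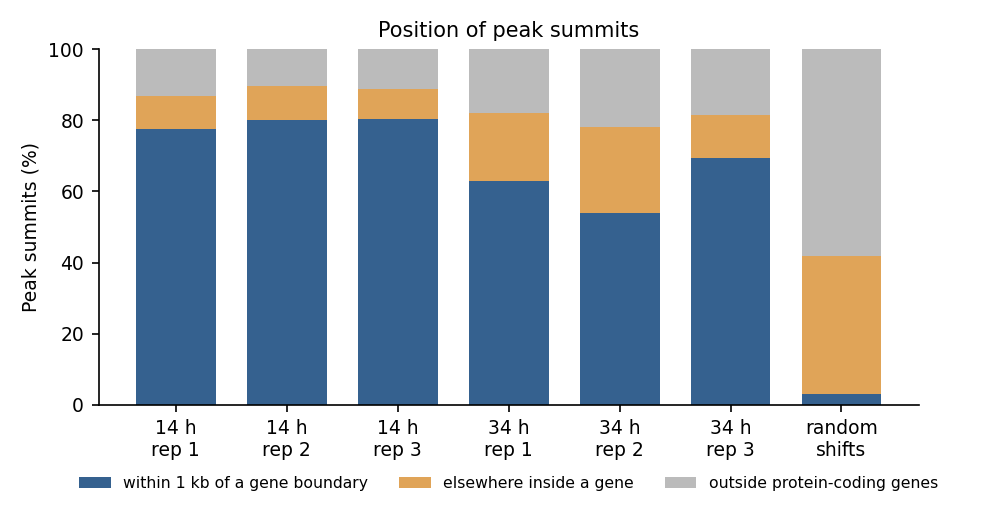
Percent of peak summits within 1 kb of a protein-coding gene boundary, elsewhere inside such a gene, or outside (stacked bars), for each of the 6 IP libraries and for the mean of 100 random shifts of the summits. The boundary share is 77.5% to 80.5% at 14 h, 54.0% to 69.4% at 34 h and 3.13% for the shifts.

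The 5 highest regions away from an annotated boundary lay inside genes at both times. At 14 h these were Sgo1, the centromeric cohesion protector gene (chromosome 17, 53689113 to 53689543, fold 26.6 ± 5.46), Mtfr2, Nemp2, Nup160 and Ccdc15. At 34 h they were Poc1a, a centriole gene (chromosome 9, 106281050 to 106281555, fold 18.2 ± 2.33), Wdr62, Sgo1, Mtfr2 and the Fanconi anaemia gene Fancm. Exons and introns were not resolved.

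The comparison of 34 h with 14 h asked how the sites differed as differentiation went on. The lists were longer at 34 h, with 2767 ± 2037 peaks against 964 ± 315 (SD, n = 3 each), a ratio of 2.87. This did not exceed the spread between libraries (exact two-sided permutation test, p = 0.2), and without replicate 2 of 34 h the ratio was 1.70. Mean IP depth differed by a ratio of 1.05 (exact p = 0.6). The narrowest peak, which the caller sets to its fragment length, was 147 ± 19.1 bp at 14 h and 167 ± 20.0 bp at 34 h (exact p = 0.3). Over the 6 libraries it rose with the log2 number of peaks, with Pearson's r of 0.937 (exact permutation p = 0.00556, adjusted over 4 tests 0.0222) and Spearman's rho of 0.928 (exact p = 0.0222, adjusted 0.0444). Without the 2 libraries farthest from the median, r was 0.862. At each time the library with the widest narrowest peak also had the most peaks, and within a time 3 libraries are too few for a correlation. The input of 34 h was 1.44 times as deep as that of 14 h.

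**Figure D3:**
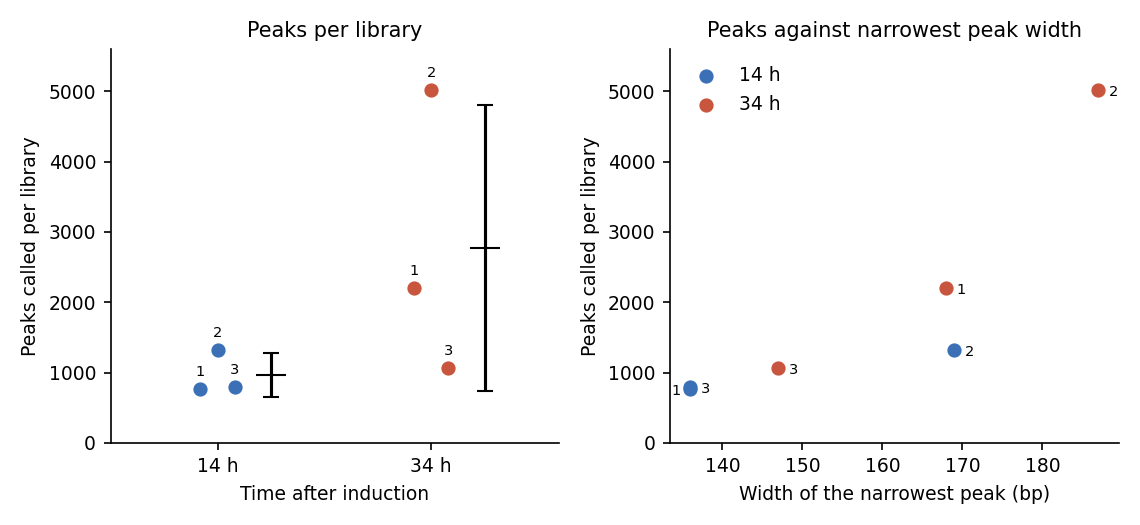
Left, number of called peaks in each IP library at 14 h and 34 h (points, numbered by replicate; black marks show mean ± SD, n = 3). Right, the same numbers against the width of the narrowest peak in bp, which ranges from 136 to 187 bp; the library with the widest one, 34 h replicate 2, has 5025 peaks.

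Most sites of 14 h were found again at 34 h. Of 856 regions found in at least 2 libraries at 14 h on chromosomes 1 to 19, X and Y, 688 (80.4%) overlapped such a region of 34 h, and 668 of 2010 regions of 34 h (33.2%) overlapped one of 14 h. Random shifts gave 0.0536% and 0.0272% (one-sided permutation p = 0.001 each, the smallest that 1000 shifts can give). The first share was 65.1% with lists of equal length. Without replicates 1, 2 and 3 of 34 h in turn it was 63.4%, 61.1% and 78.2%, and without a library of 14 h 82.8% to 91.6%. The second share was 70.3% with lists of equal length. It was 54.8% without replicate 1 and 60.8% without replicate 2 of 34 h, where all regions of that time numbered 959 and 837 in place of 2016. By gene, 848 had a region at 14 h and 1595 at 34 h, with 705 at both, where independent lists would share 61.8. Within a time, 74.2% of a library's peaks at 14 h and 59.7% at 34 h overlapped a peak of another library on average, and 53.5% did so across times (shifts 0.0208, 0.0631 and 0.0418%). None of these shifts keeps regions near gene boundaries, where most peaks lay. Sets of peaks gathered at boundaries would tend to exceed them in any case, so the shifts show only more overlap than at random positions. Libraries of the same time share an input, so part of the overlap within a time may come from it, and this could not be simulated without reads; libraries of different times do not share one.

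Across the 6 libraries, 429 of 5573 merged regions had a peak in all 6, 262 in all 3 libraries of 34 h and none of 14 h, and 8 the reverse. The 34 h set was led by regions at Zfyve1 (chromosome 12, 83597066 to 83597482, fold 9.11 ± 0.682), at Evi5l (chromosome 8, 4165913 to 4166398, fold 9.77 ± 2.92), at the Notch target gene Hes1 (chromosome 16, 30065081 to 30065391, fold 9.32 ± 2.44) and at Lrig2 (chromosome 3, 104511672 to 104512328, fold 10.5 ± 2.94). Further ones lay inside H3f3b, the gene of a replication-independent histone, and inside Chd2, Maml3 and H2bc6. H2bc6 is a replication-dependent histone gene, and its region lay outside the 1 kb boundary window. The remaining 2 of the 10 highest lay outside protein-coding genes, on chromosome 2 (119594107 to 119594402) and chromosome 5 (149228932 to 149229312). The 8 regions of 14 h lay at Bcl7a (chromosome 5, 123345177 to 123345479, fold 10.0 ± 2.79) and Meaf6 (chromosome 4, 125084959 to 125085296, fold 9.08 ± 2.57), inside Zfp423, Rcc2, Cntln, Atn1 and Plec, and outside genes on chromosome 1 (88745373 to 88745640). Of 258 regions of the 34 h set on the standard chromosomes, 55.8% touched a gene boundary window, and of 428 in all 6 libraries 86.0% did. Regions in all 6 libraries are selected for strong peaks and those of the 34 h set had low folds, and in every library the boundary share was lower in the bottom part by fold than in the top part, so this difference may come from detection alone. The 258 regions held 0 cell cycle genes and 0 histone genes of the fixed lists at a boundary, and the 428 held 21 and 12. A region with a peak in any 14 h library cannot enter the 34 h set. With any library, 37 of 48 cell cycle genes and 23 of 63 histone genes had a region at 14 h. Few members could thus enter, and the counts of 0 do not set the 34 h regions apart. With lists of equal length, regions of a single time numbered 53 for 34 h and 61 for 14 h. Without replicate 3 of 34 h the former was 1070, and the latter was 42 without replicate 2 of 34 h, 37 without replicate 1 of 14 h and 16 without replicate 3 of 14 h. With a library left out, only the libraries left had to hold, or lack, a peak, so these counts follow a looser rule.

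Of the cell cycle genes, 28 had a region at both times, 4 only at 14 h and 1 only at 34 h (exact McNemar test, adjusted p = 1.0 over 16 lists). Histone genes had 11 members only at 34 h and 0 only at 14 h (exact McNemar test, adjusted p = 0.0156). Of histone genes without a region at 14 h, 24.4% had one at 34 h, against 4.19% of other genes (odds ratio 7.62, adjusted p = 1.58e-05, Fisher's exact test). These 11 genes lay in 8 distinct regions. By Fisher's exact test the call ended with lists of equal length, where 2 were gained and 4 lost (adjusted p = 0.127), without replicate 1 of 34 h, with 0 gained (adjusted p = 1.0), and without replicate 2, with 1 gained (adjusted p = 0.890). It also ended where all 3 libraries were required, with 2 gained (Fisher's exact test, adjusted p = 0.398), and the McNemar call ended at a −log10 q of at least 5 (exact adjusted p = 0.0625). With close-neighbour genes left out 4 were gained and 0 lost, which ended the McNemar call (exact adjusted p = 1.0) and kept that of gains (Fisher's exact test, adjusted p = 0.0142). Cell cycle genes passed the test of gains without replicate 2 of 14 h, with 6 gained (Fisher's exact test, adjusted p = 0.00342), or replicate 3, with 5 gained (adjusted p = 0.0121). In the other direction, 0 were gained and 9 lost without replicate 1 of 34 h, without replicate 2 of 34 h, and at equal length (exact McNemar test, adjusted p = 0.0625 each). With a library left out, its time needed regions in 2 of 2 libraries and the other time in 2 of 3. Leave-outs, for histone and cell cycle genes alike, therefore compare the times under unequal rules. Olfactory receptors gained 0, against 4.46% of other genes (adjusted p = 1.14e-20, Fisher's exact test). The other 13 lists did not pass, with gains of 0 to 6 members, although KLF and SP transcription factors passed with close-neighbour genes left out, with the 5 kb window, with all 3 libraries required, without replicate 1 or replicate 2 of 34 h, and, as 5 more of these lists did, with any library. Per library with lists of equal length, cell cycle genes had a peak in 60.4% ± 3.61 at 14 h and 45.1% ± 3.18 at 34 h (SD, n = 3; exact p = 0.1, the smallest possible), with no overlap between times. A cut by rank drops members wherever more other sites compete, and with all peaks the shares of 65.3% and 60.4% differed by less than the spread between libraries (exact p = 0.7). At equal length, chromatin modifiers went from 9.40% to 4.27%, and KLF and SP transcription factors in the other direction, from 2.56% to 8.97%. Both also reached an exact permutation p of 0.1. These p-values were not adjusted over the lists.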

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

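The tests of explanations in this part were chosen after the results had been seen, except the count of splits of the libraries. Results are listed here because the members of a gene list were gained at 34 h more or less often than other genes, by Fisher's exact test. Of replication-dependent histone genes without a region at 14 h, 24.4% had one at 34 h, against 4.19% of other genes. Of olfactory receptor genes, 0.0% did, against 4.46% of others. Olfactory receptors had 0 regions at both times, so they did not themselves change.

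Regions at cell cycle genes were the leading pattern at both times. A general signal at promoters of broadly expressed genes would give regions at least as often at genes of ribosomal proteins, translation factors, oxidative phosphorylation and the proteasome. Of 280 such genes, 2.14% had a region at 14 h (exact 95% interval 0.790 to 4.61%) and 7.14% at 34 h (4.42 to 10.8%). Both lay below the cell cycle intervals of 51.6 to 79.6% and 45.3 to 74.2%, which argues against that explanation for the whole cell cycle share. Tested separately against other genes, none of the 4 lists passed at either time with at least 2 libraries required. With any library, translation factors and oxidative phosphorylation were among the lists that passed at 34 h. All 4 then passed the test of gains, so a smaller general signal is not excluded. The 4 lists were highest in replicate 2 of 34 h, at 20.7% to 35.9%, against 14.0% to 14.1% of other genes and 68.8% of cell cycle genes. Their expression was not measured here. Binding of the antibody to another protein at these genes cannot be told apart from binding to APOBEC2 at the 66.7% of members with a region at 14 h, since no library from cells without APOBEC2 was used here. A biological explanation, that APOBEC2 or a complex holding it sits at genes of cell division, remains an untested hypothesis.

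The longer peak lists at 34 h go with several technical measures. Mean IP depth differed by a ratio of only 1.05, and the deepest library had the longest list at neither time, which argues against IP depth as the cause of a ratio of 2.87; r of depth and log2 peaks was −0.057 over 6 libraries (exact permutation p = 0.897; Spearman's rho −0.257, exact p = 0.658; r 0.818 without the 2 farthest, so r rests on which libraries enter). Fragment length remains a candidate cause, with rho of 0.928 over the 6 libraries, although 34 h replicate 1 had 1.66 times the peaks of 14 h replicate 2 at 168 and 169 bp. Where each list ended also went with its length. The lowest −log10 p lay between 6.44 and 7.08 in the lists of 768, 797 and 1068 peaks. In the longer lists it lay between 5.01 and 5.34. With a −log10 q of at least 5 in every list, the ratio of peaks was 2.60. The deeper input at 34 h, by 1.44 times, cannot be told apart from time, because each time has 1 input. The time after induction also stays open; the 270 regions in all libraries of one time and none of the other compare with 83 in the highest other split, in which the 3 longest lists stood together, and 1 of 10 splits reached 270, too few splits for a share under 0.05.

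Differences of gene lists between times were weighed against list length. For histone genes, gains were counted from the shortest to the longest list of the same time, where time does not differ. At 14 h, 18.4% of histone genes without a peak in the shortest list had one in the longest, against 2.79% of other genes (odds ratio 8.18, 95% interval 3.33 to 16.5, adjusted p = 8.03e-06, Fisher's exact test), and at 34 h 60.4% against 10.5% (odds ratio 12.9, interval 7.03 to 24.6, adjusted p = 1.49e-16). Between single lists of 14 h and longer ones of 34 h the odds ratio had a median of 7.89 (1.90 to 11.5 over 8 pairs), so an excess of histone genes also came with the longer list within a time, in line with longer lists as the cause. The reported gain used regions of at least 2 libraries, so its odds ratio of 7.62 is of another form. Each comparison within a time used 1 pair of libraries, neighbouring histone genes are not independent, and a change during differentiation is not excluded. For cell cycle genes the share with all peaks differed by less than the spread between libraries (65.3% and 60.4%, exact p = 0.7), and the odds ratio at 14 h was 2.59 times that at 34 h with all peaks and 1.74 times at equal length. At equal length the difference in share, 34 h minus 14 h, was −15.3 percentage points, but a cut by rank drops members wherever more other sites compete, so this test was void and cannot tell list length from another cause. Input depth, fragment length and a change during differentiation also stay open for this part.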

How the results depend on the processing

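Alternatives were fixed before the data were examined, except leaving out genes with a close neighbour and the lists named among the other observations. Of the values that answer a comparison, 220 kept their direction and side of the threshold or stayed within 1.5 times, 27 moved and 0 reversed. The 220 include values that could not change, such as region counts of one time when a library of the other is left out. They also include the share of 34 h regions that overlapped 14 h, which went from 33.2% to 70.3% at equal length. The count is therefore no measure of robustness. Across 17 settings the odds ratio of the cell cycle list lay between 40.0 and 79.5 at 14 h and between 15.2 and 33.4 at 34 h. That of histone genes lay between 7.90 and 15.3 and between 7.29 and 18.0, with their highest adjusted p at 0.0107 (Fisher's exact test). Some of these settings, such as standard chromosomes only, leave the odds ratios unchanged by construction. The sequence-based alternatives were not run. Depth limits what is seen of weak sites, since every summit stood on at least 10 fragments.

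Counts that moved did so mostly with list length and the number of libraries required. Reproducible regions at 34 h, 2016 as reported, numbered 661 with lists of equal length, 826 when all 3 libraries were required, and 837 to 2016 with a library left out. Regions of all 34 h libraries alone, 262, numbered 53 at equal length, 1178 with at least 2 libraries, and 264 to 1070 with a library left out. Regions of 14 h alone, 8, numbered 61, 47 with at least 2 libraries, 13 with 50% reciprocal overlap, and 10 to 42 with a library left out. Using any library gave 4 lists above other genes at 14 h, 8 above and 2 below at 34 h, and 7 with more gained genes and 5 past the McNemar test. Lists with more gained genes numbered 0 at equal length, 2 with the 5 kb window, 2 with close-neighbour genes left out (histones with KLF and SP factors in both) and 1 to 2 with a library left out; the list counted was KLF and SP factors in place of histones without 34 h replicate 1, without 34 h replicate 2, and when all 3 libraries were required. Lists past the McNemar test numbered 0 at a −log10 q of at least 5, at equal length and with all 3 libraries, and 0 to 1 with a library left out. The McNemar call of histone genes also ended with close-neighbour genes left out (4 gained, exact adjusted p = 1.0). With a library left out the rule itself changed, since reproducible regions of its time then needed both libraries left. Time-specific regions then depended only on the libraries left. How much of the moves came from this, and their other causes, were not tested.

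In 28 cases the odds ratio of a list that did not pass as reported crossed 1, and the cause was not tested. With any library, ribosomal proteins gave 1.24 and neural lineage 0.760 at 14 h, translation factors 1.01 at 14 h and 3.43 at 34 h (adjusted p = 1.72e-05, Fisher's exact test), and at 34 h oxidative phosphorylation 1.97 (adjusted p = 0.0242), interferon response 0.792 and TGF-beta and BMP signalling 1.98. Without close neighbours, values were 1.03 for ribosomal proteins, 1.56 for translation factors and 2.53 for oxidative phosphorylation at 14 h, and 1.24 for the last at 34 h. The 5 kb window gave 1.03 for translation factors, 0.836 for interferon response and 1.80 for adipogenic, cartilage and bone lineages at 14 h. Equal length gave 0.625 for myogenic factors at 14 h, and 0.614 for ribosomal proteins and 1.00 for oxidative phosphorylation at 34 h. All 3 libraries gave, at 14 h, 0.792 for myogenic factors, 1.04 for oxidative phosphorylation, 0.584 for neural lineage and 0.673 for KLF and SP factors. With a library left out, values at 14 h ran from 0.680 to 1.97 for myogenic factors, from 0.724 to 1.03 for oxidative phosphorylation, from 0.502 to 1.44 for neural lineage and from 0.532 to 2.08 for KLF and SP factors.

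With the replicate number as a block, the ratio of peaks was 2.87, the boundary difference −17.2 percentage points and the count of 34 h regions 262, each with an exact p of 0.25, the smallest that 3 pairs allow. Same-numbered libraries did not deviate together (correlations −0.0556, −0.150 and −0.0850), so the numbers were not treated as pairs, and no library correlated best with its own number.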

Other observations

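All lists and tests in this part were chosen after the data had been seen, and the lists were tested on the same data, so their p-values are descriptive. Kinetochore and spindle checkpoint genes had a region at 30 of 39 members at 14 h and 32 of 39 at 34 h (76.9% and 82.1%; odds ratios 82.5 and 56.2, adjusted p = 8.18e-34 and 2.78e-29, Fisher's exact test). Of the 9 without a region at 14 h, 3 were gained at 34 h (33.3% against 4.22% of other genes, adjusted p = 0.0262, Fisher's exact test), and 1 of the others was lost. This gain rests on 3 genes. Per library with all peaks the share with a peak was 76.1% ± 3.92 at 14 h and 79.5% ± 7.69 at 34 h (SD, n = 3, exact permutation p = 0.7). With lists of equal length it was 74.4% ± 4.44 and 70.1% ± 3.92 (exact permutation p = 0.3), but a cut by rank drops members wherever more other sites compete. At 14 h Incenp, Ttk, Ndc80, Espl1, Cenpf and Knl1 led them. Genes of homologous recombination and the Fanconi anaemia pathway had 21 and 23 of 34, led at 14 h by Brca1 (fold 29.1 ± 6.80), Palb2 and Brca2. Within the cell cycle list, 16 and 14 of 20 G1/S members and 13 and 12 of 14 G2/M members had a region. G1 cyclins, their kinases and inhibitors had 2 of 12 at both times (adjusted p = 0.102 and 0.254, Fisher's exact test).

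Nucleoporin genes had 11 of 20 at both times and kinesin genes 13 of 38 at both times, with Kif18b, Kif20a, Kif23 and Kif2c, kinesins of mitosis, among the leading members. Heat shock proteins and chaperonins had 2 of 36 at 14 h and 12 of 36 at 34 h, of which 10 were gained (29.4% against 4.19% of other genes, adjusted p = 9.07e-06, Fisher's exact test). Each of the 10 had its region in only 2 of the 3 libraries of 34 h, and Hspd1 and Hspe1 share a region. Per library with all peaks, 10.2% ± 8.49 and 31.5% ± 22.5 of the heat shock and chaperonin genes had a peak (SD, n = 3, exact permutation p = 0.2). With lists of equal length the shares were 5.56% ± 2.78 and 8.33% ± 4.81 (exact permutation p = 0.7). A cut by rank drops members wherever more other sites compete, so the latter cannot tell list length from another cause. The 8 added lists besides the heat shock and kinetochore lists did not pass the test of gains, with adjusted p from 0.0523 to 1.0. Aminoacyl-tRNA synthetases had 2 and 4 of 20 (adjusted p = 0.226 and 0.0761, Fisher's exact test), led by Vars (fold 30.2 ± 8.66 at 14 h), and immediate early genes 1 of 20 at both times, which was Myc (fold 12.3 ± 1.82 at 14 h).

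Of 408 annotated tRNA genes, 16 were touched by a reproducible region at 34 h, against 0.146 on average in random shifts (permutation test, adjusted p = 0.00799 over 8 tests), and 1 at 14 h (adjusted p = 0.104). The shifts do not keep regions near genes, so this excess does not set tRNA genes apart from other positions at genes. By library the counts were 1, 3 and 1 at 14 h and 15, 46 and 5 at 34 h (exact two-sided permutation p = 0.1, the smallest possible). At each time the count was highest in the longest list. Of 1004 snRNA, 1340 snoRNA and 1228 miRNA genes, no more than 2 were touched at either time.

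Among the 428 regions of all 6 libraries on the standard chromosomes, the 21 at cell cycle genes had a median fold percentile of 50.9 ± 4.73 at 14 h and 55.6 ± 5.28 at 34 h (SD, n = 3; exact permutation p = 0.3). Across these regions, which are not independent replicates, the rank correlation of fold averaged 0.891 between libraries of 14 h, 0.826 between those of 34 h and 0.733 across times. Of the 5573 merged regions, 2723 were in 34 h replicate 2 alone.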
